A study of Mus musculus with 4 samples.

How the data were processed

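Global run-on sequencing (GRO-seq) was performed on nuclei of primary mouse splenic B cells. The method lets engaged RNA polymerases extend their transcripts in isolated nuclei and sequences the labelled nascent RNA, with its strand. Per the labels' protocols, the cells came from Fucci-EGFP+ C57BL/6 mice, whose fluorescent reporter follows the cell cycle, and were activated in culture with LPS, IL4 and an Rp105 stimulus. Nocodazole, which blocks cells in mitosis, was added at 100 ng/ml at 42 h after isolation and left for 6 h. EGFP+ cells were then sorted, returned to culture and sorted again for early G1 cells. The labels give 1.5 h in culture for both early G1 libraries, while the deposited name of replicate 1 says 1 h, and which holds for it is unknown. There were 2 libraries of unsynchronized cells and 2 libraries of early G1 cells, and the groups and replicate numbers were taken from the sample titles. Nocodazole and the return to culture are recorded for the early G1 libraries alone. Effects of these steps can therefore not be told apart from those of the cell cycle phase. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

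The authors deposited a list of regions of convergent transcription for each library, per the file headers. Such regions carry sense and antisense nascent transcripts over the same DNA. The submitters' processing notes name BWA 0.7.12, HOMER and the mouse build mm9. How regions were called is not given in the sources used here. Each region in the deposited files has a position and a signal, which the authors named a geometric mean. Its scaling is not stated, and was examined in the values. The square of the signal times the region length was a whole multiple of a single constant in each library. This held for 100% of the 2833, 2351, 3384 and 2164 regions tested in unsynchronized replicates 1 and 2 and early G1 replicates 1 and 2 (multiples below 5000, tolerance 0.1). The signal therefore behaves as the geometric mean of a sense and an antisense read count, divided by length and by a library constant. If that constant scales to length and library size as RPKM does, the unsynchronized libraries held 14720000 and 13480000 reads and the early G1 libraries 8170000 and 9520000 reads, to the nearest 10000. These sizes are inferred and stated nowhere. "Reads" below means this recovered geometric mean of the 2 strands' read counts.

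The median region held 159 and 182 reads in the unsynchronized and 143 and 167 reads in the early G1 libraries. Counting error alone is then at least 5.24% to 5.92% of the median region's signal, a lower bound reached when the strands carry equal reads. This bound covers counting error only, and duplicates of a molecule could not be examined in the region lists. Between 0.479% and 0.719% of the regions of a library had a signal of 0.

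The files name no genes. They use mm9, whereas the gene table at hand is of GRCm38, and on 8 of 21 chromosomes the deposited regions reach beyond the last gene of that table. Coordinates were not converted. Regions are therefore given by mm9 position, counted from 1, and the planned comparisons per gene and per gene list (cell cycle, histone, immunoglobulin and cell type marker lists) were not made.

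Regions of the 4 libraries were merged where they shared at least 1 base. A library's value in a merged region was the length-weighted mean of its own regions there. Regions called in all 4 libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(signal + 1), with the authors' scaling kept. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(signal + 1) scale, which understates the change of low regions. Signal times length was summed over 1 Mb bins and tested in the same way. Overlaps were computed with bedtools 2.31.1, and single values were compared between groups by an exact two-sided permutation test, whose smallest possible p is 0.333 with 2 against 2 libraries. Since regions were called in each library separately, a region missing from a library has no value there, and presence is described by counts without a test.

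Data were simulated with the levels of the 4972 merged regions and with spreads drawn from the distribution that limma fitted to them. Regions were independent and no library was shifted, so the simulation follows the test's own model and does not give error rates for these libraries. The test called 64 of 100 regions changed 4-fold and 5 of 100 changed 2-fold, with 8 false calls. In the simulated 1520 bins it called 0 of 100 at either fold.

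The rule for the regions named was fixed before the data were examined. It takes the 12 largest changes in each direction among those past the threshold whose groups did not overlap. Where fewer than 6 passed in a direction, as for decreases, it takes the 6 largest non-overlapping changes with a mean signal above the median. It adds the 10 highest mean signals and the 5 longest regions found in each group alone. Outside this rule, the decrease at chr4:118098101-118109040 and the 3 smallest of the 15 increases are named because they passed, and were chosen after their values were seen. Alternatives were other scalings, pseudocounts, filters, merging distances and region values, a block for the replicate number, and the omission of each library. Count-based tools were not applicable.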

Results

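Regions of convergent transcription were listed for 4 GRO-seq libraries, 2 of unsynchronized activated B cells and 2 of sorted early G1 cells. The unsynchronized libraries held 12538 and 11961 regions and the early G1 libraries 12768 and 10708. These covered 22305 and 18562 kb against 19246 and 15551 kb, with length-weighted mean signals of 17.3 and 26.2 against 31.1 and 34.5. The inferred size of the early G1 libraries was 0.627 times that of the unsynchronized libraries. If the inference holds, depth differed with the group throughout. The reads of the median region differed less, at 0.906 times, but each library's median is over its own called regions. In the regions called in all 4 libraries, unscaled reads had a median log2 change of -0.25, early G1 minus unsynchronized.

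The first comparison asked how alike the sets of regions were. The 4 lists merged into 20175 regions, of which 4972 (24.6%) were called in all 4 libraries and 8056 (39.9%) in a single library. Of the 7942 merged regions called in both unsynchronized libraries, 87.4% were also called in at least 1 early G1 library. Conversely, 89.4% of the 7031 regions called in both early G1 libraries were called in at least 1 unsynchronized library. By bases, the unsynchronized libraries shared 45.9% of their union (Jaccard index) and the early G1 libraries 37.5%. Pairs taken across the groups shared 36.5% to 39.5%, so the early G1 replicates were no more alike than early G1 replicate 1 and unsynchronized replicate 1. The index within groups minus that between groups was 4.30 percentage points on average, and -0.65 without unsynchronized replicate 2.

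In 1004 merged regions a call was made in both unsynchronized libraries and in neither early G1 library, and in 747 the reverse. A missing call does not show that transcription was absent. These 1751 regions compare with 1218 for the split of replicate 1 against replicate 2 and 900 for the crossed split of the same libraries. Unsynchronized-only regions were weak, with a median signal of 8.91 against 19.9 for regions shared by all 4 libraries. The early G1-only regions had a median of 18.3 against 27.2. The balance of these counts depended on the signal threshold. Above the 25th percentile of all signals (8.51), 438 regions were called in the unsynchronized libraries alone and 957 in the early G1 libraries alone. The 25th percentile of single libraries was 6.09 and 8.35 in the unsynchronized and 9.70 and 11.9 in the early G1 libraries. This threshold on the scaled signal thus removed a larger share of the unsynchronized regions. The 12119 regions called in at least 2 libraries were also tested. Missing signals were set to the lowest value of the library, which was 0 in each. Of these regions, 0 passed the threshold in limma, with 1230 higher and 1009 lower in early G1 at an unadjusted p under 0.05. A missing call thus entered as no signal, so these counts in part restate which libraries had a call.

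Long regions lacked a call in early G1 more often than in unsynchronized cells. Most had some call in both groups, but a call needed only 1 shared base and could be much shorter. For regions over 10 kb called in both unsynchronized libraries, the called length in early G1 was a median 0.561 times their own. For those of 5 to 10 kb it was 0.692 times. For regions called in both early G1 libraries, the medians in unsynchronized cells were 0.892 (over 10 kb) and 0.946 (5 to 10 kb). Of the 251 regions over 10 kb that both unsynchronized libraries held, 25 (9.96%) were called in neither early G1 library, whereas 1 of 138 such early G1 regions (0.725%) was called in neither unsynchronized library. Over 5 kb, the counts were 64 of 671 and 7 of 444. The other splits of the libraries gave 31 and 37 regions over 5 kb in 1 pair alone, against 71 for the groups. The groups differed less among short regions. Below 1 kb, 15.9% of the regions called in both unsynchronized libraries and 15.3% of those called in both early G1 libraries were missing from the other group. No length class was part of the planned comparisons, and the class of 5 kb was chosen after the data had been examined.

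**Figure D1:**
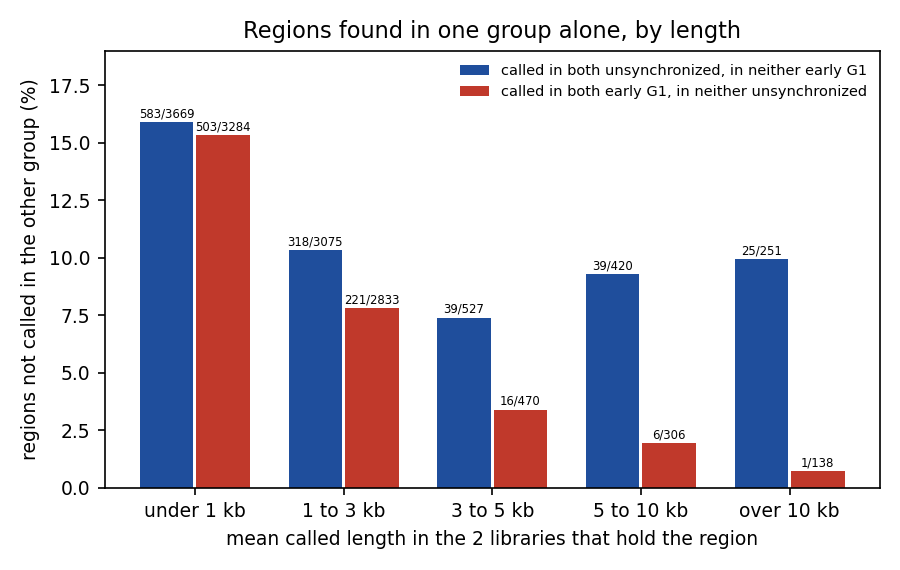
Share of regions called in both libraries of a group and in neither library of the other (percent), by mean called length. Numbers above the bars are regions missing over regions held. The unsynchronized bar is 9.96% and the early G1 bar 0.725% in the class over 10 kb, while the bars under 1 kb are 15.9% and 15.3%.

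The longest region called in the unsynchronized libraries alone was chr13:85338907-85376732, which spans 37826 bp and had a signal of 16.4 ± 2.80 (SD, n = 2) on 7159 and 8000 reads. Next came chr14:28280058-28313560 with a signal of 10.9 ± 0.19 and chr3:19110338-19140525 with 13.5 ± 4.22 (SD, n = 2). The fourth and the fifth were chr2:105789161-105816522 at 6.69 ± 0.27 and chr11:96809853-96836805 at 10.05 ± 2.54 (SD, n = 2). In the early G1 libraries alone, the longest was chr3:40612515-40628353, with 15839 bp and a signal of 21.6 ± 6.71 (SD, n = 2) on 1028 and 3978 reads. It was followed by chr7:135833525-135843225 at 26.0 ± 13.7 and chr2:38867431-38875972 at 22.3 ± 4.43 (SD, n = 2). The remaining regions were chr3:106531191-106539475 at 20.7 ± 1.28 and chr7:29178257-29186120 at 12.3 ± 3.37 (SD, n = 2).

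Counts of regions over 10 kb were 331 and 238 in the unsynchronized libraries and 140 and 184 in the early G1 libraries, and thus 284.5 ± 65.8 against 162.0 ± 31.1 (SD, n = 2). The libraries of the groups did not overlap in this count (exact permutation p = 0.333, the smallest possible). They did not overlap in inferred library size either, and the 4 counts ranked as the library sizes did. The difference of -122.5 regions was -76 without unsynchronized replicate 1 and -169 without unsynchronized replicate 2. The number of all regions, 12250 ± 408 against 11738 ± 1457 (SD, n = 2), differed by less than the spread between replicates.

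The second comparison asked where the level of convergent transcription differed in regions called in all 4 libraries. In early G1 cells 15 of 4972 regions were higher and 2 lower (limma, adjusted p under 0.05). All 17 had both early G1 libraries on the same side of both unsynchronized libraries. At an unadjusted p under 0.05, 693 were higher and 47 lower. The level of all shared regions lay higher in early G1 with the authors' scaling, with a median log2 change of 0.41 (1.33-fold) and 78.0% of the regions above 0. This median was 0.21 without unsynchronized replicate 1 and 0.60 without unsynchronized replicate 2, and the 2 splits that mix the groups gave medians of 0.18 and 0.21. After each library was divided by its median, 0 of the regions passed the threshold in limma, with 212 higher and 285 lower at an unadjusted p under 0.05. The 17 kept their direction, but none their call, at log2 changes of 1.66 to 7.55 for the increases and of -2.59 and -4.16 for the decreases. A lost call did not always go with a smaller difference. At chr14:66424650-66426302 the log2 change went from -2.16 (SE 0.43) to -2.59 (SE 0.35), while the limma adjusted p rose from 0.0496 to 0.22. At chr6:124689026-124691322 it went from 3.39 (SE 0.60) to 2.95 (SE 0.76), and the limma adjusted p from 0.036 to 0.40. The count also moved when a library was left out, in fits where the spread comes from the group that keeps both libraries and the lone library is assumed to vary like it. It was 19 without unsynchronized replicate 1, 1 without unsynchronized replicate 2, 68 without early G1 replicate 1 and 119 without early G1 replicate 2. Of the 17 regions, 4, 0, 16 and 16 remained in these settings. With regions merged within 1 kb, 1 of the 17 remained called and 16 kept their direction. Called lengths lay within 1.5 times of each other in all 4 libraries for only 4 of the 17. The replicates differed with a median residual SD of 0.39 on the log2 scale, against a counting error of at least 0.063.

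**Figure D2:**
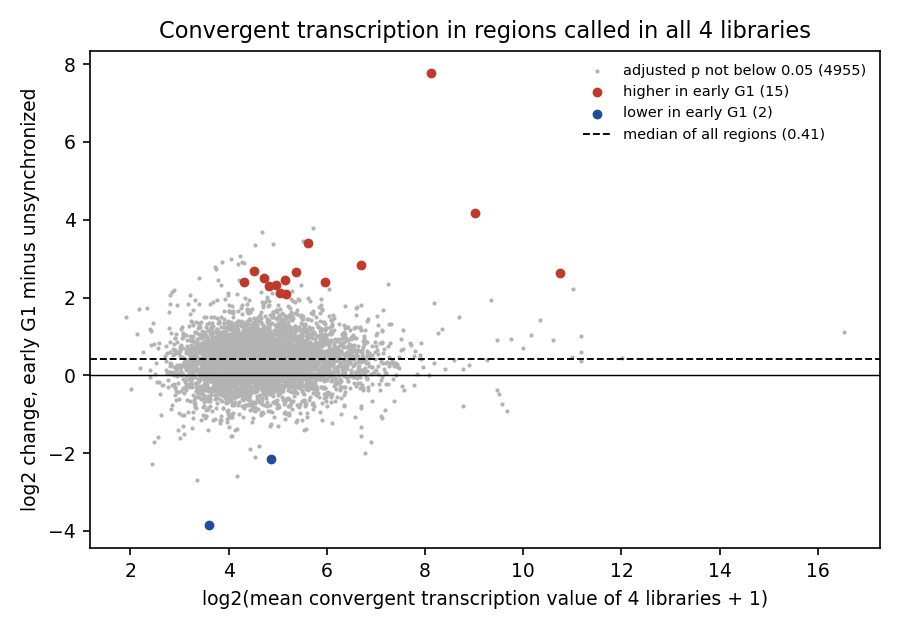
Log2 change of convergent transcription, early G1 minus unsynchronized, against log2 of the mean signal + 1, for the 4972 regions called in all 4 libraries. The dashed line is the median of 0.41. Of the coloured regions, 15 lie above it at an adjusted p under 0.05 (limma, authors' scaling) and 2 lie below 0.

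The mitochondrial genome, which is transcribed from both strands, held a single merged region at chrM:11187-16292. Its signal rose from 474 ± 28.0 to 2966 ± 742 (SD, n = 2), a log2 change of 2.62 (SE 0.47, limma adjusted p = 0.036) and of 2.21 beyond the median shift. With merging within 1 kb its change was the same, but its adjusted p was 0.081. Mitochondrial signal made up 0.585% ± 0.066 of all signal in unsynchronized cells and 2.71% ± 1.003 in early G1 cells (SD, n = 2, without the chromosome 16 region of highest signal). It was higher in both early G1 libraries than in both unsynchronized libraries. The run-on used isolated nuclei, and the mitochondria left in each preparation were not measured here. A difference in that content can therefore not be told apart from one in mitochondrial transcription.

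On chromosome 13, 3 regions within 312 kb rose in early G1. At chr13:21809885-21812319 the signal rose from 10.05 ± 1.49 to 59.1 ± 5.14 (SD, n = 2), a log2 change of 2.45 (SE 0.41, limma adjusted p = 0.036) and of 2.03 beyond the median shift. Its called length was 1011 and 977 bp in the unsynchronized and 2402 and 2243 bp in the early G1 libraries, and with merging within 1 kb its log2 change was 1.39 (adjusted p = 0.31). The region chr13:21872938-21874884 rose from 18.9 ± 1.86 to 104.6 ± 4.62, a log2 change of 2.41 (SE 0.40). Merged with the neighbour within 1 kb, however, it changed by -0.95 (adjusted p = 0.41). The third region, chr13:22121066-22122063, rose from 37.6 ± 1.02 to 999 ± 1019, a log2 change of 4.17 (SE 0.63, limma adjusted p = 0.024). Its early G1 libraries had signals of 1719 and 278, and its log2 change was 2.85 without early G1 replicate 1 and 5.48 without early G1 replicate 2. It did not pass without unsynchronized replicate 1 or 2 (adjusted p = 0.11 and 0.33). Of the 7 shared regions in this interval, 4 were above 0 and 3 below, with log2 changes down to -1.15.

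The remaining increases had signals of 4.29-fold to 10.5-fold, apart from chr19:12083017-12084043. There, both unsynchronized libraries were at the floor with 0 and 2 reads, while early G1 replicates 1 and 2 had 8630 and 621 reads, and with merging within 1 kb the log2 change was 1.91 (adjusted p = 0.29). The region chr6:124689026-124691322 rose from 10.2 ± 10.7 to 86.0 ± 1.35 (SD, n = 2) and chr6:145289453-145290101 from 27.1 ± 19.6 to 178.5 ± 63.5. Without unsynchronized replicate 1 their log2 changes were 4.57 and 3.60, and without unsynchronized replicate 2 they were 2.21 and 2.05, where neither passed (adjusted p = 0.33 for both). In the former region unsynchronized replicate 2 held 9 reads on 250 bp. Increases of 6.44-fold and 6.26-fold were measured at chr11:102994455-102996031 and chr4:133640636-133651032, but log2 changes of only 1.06 and 1.47 with merging within 1 kb (adjusted p = 0.31 and 0.24). At the latter, unsynchronized replicate 1 held 10397 bp with 2452 reads, more than the 1822 and 1047 reads of the early G1 libraries on 2377 and 2418 bp. The rest of the 12 largest were chr8:11556058-11558001 (5.72-fold), chr3:61166792-61168454 (5.28-fold) and chr16:55966502-55967678 (4.99-fold). With merging within 1 kb, the log2 change of the first was 1.93 and that of the last 0.63 (adjusted p = 0.21 and 0.51). The 3 smaller increases, outside the naming rule, of 4.29-fold to 4.87-fold, were at chr10:79145177-79146229, chr5:120953031-120953682 and chr19:44326884-44328864.

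At both decreases the called length differed between the groups. At chr4:118098101-118109040 the unsynchronized libraries held regions of 10603 and 10343 bp with 2639 and 3643 reads. The early G1 libraries held 185 and 123 bp with 2 and 0 reads there (limma adjusted p = 0.045). The call was lost with a pseudocount of 0.1 (limma adjusted p = 0.23), with merging within 1 kb (0.090) and with the replicate block (0.096). It was also lost without unsynchronized replicate 1 or 2, at log2 changes of -4.15 and -3.55. The call remained without the limma trend (adjusted p = 0.014). It also remained for signal times length (log2 change -7.63, adjusted p = 0.0067) and for unscaled reads (-10.8, adjusted p = 0.033), which both take in the called length. The signal at chr14:66424650-66426302 fell from 46.1 ± 7.89 to 9.72 ± 3.05 (SD, n = 2, limma adjusted p = 0.0496). As signal times length, its log2 change was -0.45 (adjusted p = 0.69), and the region was 325 and 368 bp long in the unsynchronized and 871 and 1653 bp long in the early G1 libraries.

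**Figure D3:**
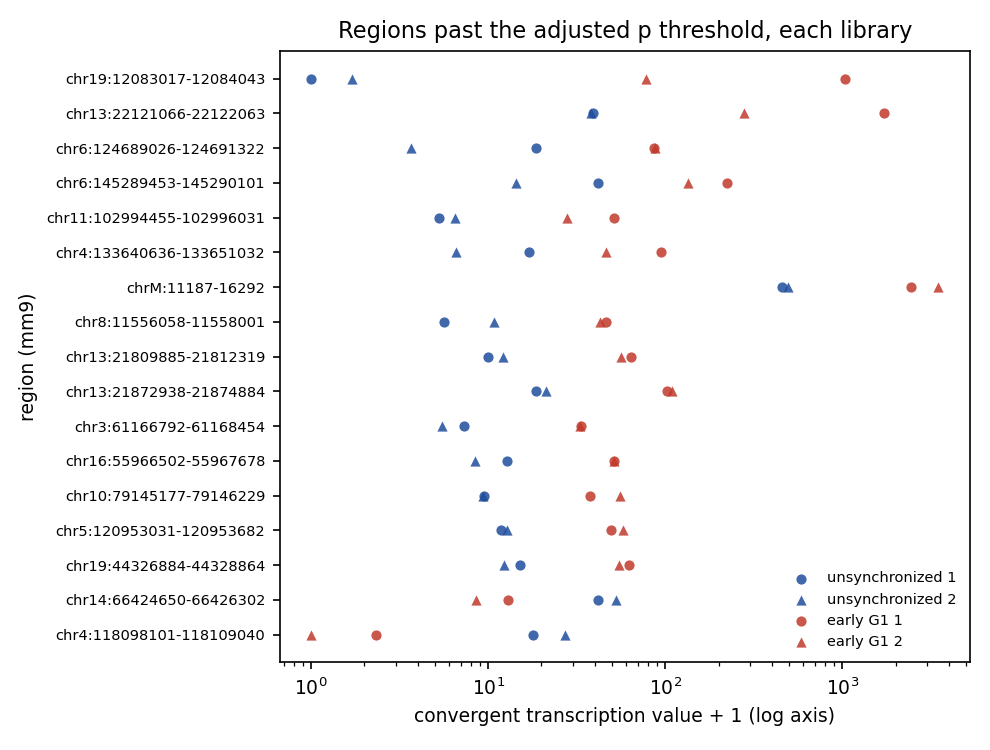
Signal + 1 on a log axis in each of the 4 libraries for the 17 regions past the adjusted p threshold with the authors' scaling. In the upper 15 regions both early G1 libraries lie above both unsynchronized libraries, and in the lower 2 both lie below.

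Another 5 regions with large negative changes did not pass the test. Their log2 changes ran from -2.004 at chr6:83057946-83059271 (SE 0.64, limma adjusted p = 0.20) to -1.31 at chr9:44215872-44226155 (adjusted p = 0.28). Between these lay chr5:124777578-124778664 at -1.72, chr14:28049871-28052909 at -1.40 and chr11:117515381-117517354 at -1.38. The 2 last named changed sign when signal times length was compared, to 0.09 and 0.56. With merging within 1 kb, chr6:83057946-83059271 was at -0.47, and chr5:124777578-124778664 was at -0.42 as signal times length. Leaving out an early G1 library moved 3 of them widely: chr6:83057946-83059271 to -3.17 without replicate 1 and -0.84 without replicate 2, chr9:44215872-44226155 to -2.20 and -0.43, and chr14:28049871-28052909 to -0.43 and -2.36. Each passed at the larger size (limma adjusted p = 0.00074, 0.027 and 0.010), with the spread taken from the unsynchronized libraries alone.

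Of the 10 regions of highest mean signal, only the mitochondrial region passed the test. At chr16:35981508-35981979 the signal was 58815 ± 3441 in unsynchronized and 130624 ± 42748 in early G1 cells (SD, n = 2, limma adjusted p = 0.51). This region of 472 bp held 4.85% to 8.52% of a library's signal. Next in mean signal were chr11:68937711-68938528 with 3373 ± 542 and 4885 ± 2308, and chr11:48670027-48670583 with 1847 ± 183 and 2810 ± 545 (SD, n = 2). The regions chr11:68854308-68854901, chr1:134930496-134931003, chr7:105963891-105964382, chr9:65049233-65049652 and chr2:57034406-57034967, had log2 changes between 0.36 and 1.42 and did not pass either. Replicates differed widely at some of them. At chr2:57034406-57034967 the signals were 1136 and 374 in unsynchronized and 2431 and 1244 in early G1 cells. At chr11:68854308-68854901 they were 1458 and 1321 against 4881 and 1582. Of the 9 regions that did not pass, the largest log2 change was at chr8:97227431-97228024, with 762 ± 383 and 3353 ± 313, at 2.23 (SE 0.51, limma adjusted p = 0.090), and at 1.10 with merging within 1 kb. It passed when regions of low mean, of few reads or of dissimilar length were left out. These filters test fewer regions and fit the spread anew to those kept.

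The third comparison asked whether larger stretches of the genome differed. Of 1520 bins of 1 Mb covered in all 4 libraries, 2 were lower in early G1 cells and 0 higher (limma, adjusted p under 0.05), with 178 higher and 23 lower at an unadjusted p under 0.05. A bin's value is a sum over regions called separately in each library, so a region without a call adds 0, and the 2 calls restate missing long regions. Both bins were singled out after their values were seen. The bin at 85000001 to 86000000 on chromosome 13 (limma adjusted p = 0.038) had 38.1 and 37.8 kb covered in the unsynchronized and 3.001 and 1.32 kb in the early G1 libraries, with mean signals of 13.5 and 17.3 against 11.8 and 23.1. The region chr13:85338907-85376732 held 94.4% and 90.7% of the unsynchronized sums. Without it, the sums of signal times kb were 29.1 and 60.9 against 35.3 and 30.4, which overlap. In the bin at 105000001 to 106000000 on chromosome 2 (limma adjusted p = 0.038), 27.2 and 31.5 kb were covered against 0.873 and 0.804 kb, with mean signals of 6.96 and 6.50 against 8.88 and 15.2. Here chr2:105789161-105816522 held 95.2% and 84.8% of the unsynchronized sums. Without it, the sums were 9.03 and 31.1 against 7.75 and 12.2, which overlap as well. With the replicate number as a block, 11 bins were higher and 2 lower (limma, adjusted p under 0.05). After division by the library median, only the chromosome 13 bin passed (limma adjusted p = 0.045), and 96 bins were higher and 66 lower at an unadjusted p under 0.05. With a library left out, where the spread again comes from a single group, 0 bins were called without unsynchronized replicate 1 or 2 (106 and 123 higher, 15 and 16 lower at an unadjusted p under 0.05, limma). There were 32 higher and 28 lower without early G1 replicate 1, and 52 higher and 24 lower without early G1 replicate 2. By chromosome, 7 of 22 shares of signal separated the groups, 3 higher and 4 lower in early G1, where chance separates 33.3% of such comparisons. The X chromosome held 1.40% ± 0.086 of the signal in unsynchronized and 1.38% ± 0.12 in early G1 cells (SD, n = 2), a difference within the spread.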

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

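Alternatives marked as added were chosen after seeing the data: signal times length, unscaled reads, minimum reads, zero signals or top regions left out, similar lengths, the shallowest library's threshold, and all alternatives for regions over 5 kb. The count of changed regions (17 with the authors' scaling) was 0 after division by the library median and 0 after quantile normalization. It was also 0 when regions called in at least 2 libraries entered with missing signals at 0, the lowest value of each library. It was 4 with the replicate number as a block, 2 without the limma trend, 2 with the highest signal in a region and 3 with merging within 1 kb. For signal times length and for unscaled reads it was 1, in both cases chr4:118098101-118109040. It was 32 without regions of a mean below the 25th percentile, 43 with at least 50 reads in every library and 71 among the 1969 regions of similar length. Leaving out a library gave 1 to 119, in fits that take the spread from the group with both libraries. The cause was not tested. The filters for mean, reads and similar length test fewer regions, and limma also fitted its spread anew to the regions kept. The 17 regions kept their direction in every setting where they were measured, except 1 with merging within 1 kb. Of those measured, 15 of 16 above the 25th percentile kept their call. The median log2 change of all shared regions was 0.41, but -0.026 after division by the median and 0.0080 after quantile normalization, which remove it by construction, and -0.25 for unscaled reads. It ran from 0.21 to 0.60 without a library.

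For the 31 named regions called in all 4 libraries, results under the alternatives lost the call in 176 cases and gained it in 10. They changed sign or reached 0 in 17. In the other 356 cases sign and call status stayed, which says nothing of size. Among these, chr6:83057946-83059271 went from -2.004 to -0.47 with merging within 1 kb. Sign changes concerned regions that had not passed, except chr13:21872938-21874884, at -0.95 with merging within 1 kb. They were 0.088 at chr14:28049871-28052909 and 0.56 at chr11:117515381-117517354 for signal times length. At chr11:68937711-68938528 they were -0.0059 after division by the median, -0.23 after quantile normalization, -0.019 unscaled and -0.043 to 0.96 without a library. At chr1:134930496-134931003 they were -0.10, -0.53, -0.32 and -0.12 to 0.84 in the same order. At chr7:105963891-105964382 they were -0.0027, -0.41 and -0.23 in the first 3 settings. Quantile normalization gave 0 at chr16:35981508-35981979 and -0.37 at chr11:48670027-48670583, and chr9:65049233-65049652 ran from -0.14 to 1.94 without a library. The lowest of these came without early G1 replicate 1.

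The 2 changed bins became 1 after division by the median, 13 with the replicate block (11 higher and 2 lower), 0 with 100 kb bins and 0 to 76 without a library. The number of regions, early G1 minus unsynchronized, was -511.5, but 1447.5 above the 25th percentile and -1541.5 to 518.5 without a library. That threshold removed a larger share of the unsynchronized regions, whose scaled signals lay lower. The covered length differed by -3034 kb as deposited and by 75.2 kb above the 25th percentile, and by -4906 to -1163 kb without a library. The difference in regions over 10 kb was -122.5, and -169 to -76 without a library. The Jaccard index within groups exceeded that between groups by 4.30 points, and by -0.65 to 9.13 without a library. For the percent of regions touched, the difference was 3.14 and ran from -0.85 to 7.90. Regions called in the unsynchronized libraries alone (1004) were 438 above the 25th percentile, 375 above that of the shallowest library and 1645 to 3021 without a library. Regions called in the early G1 libraries alone (747) were 1265 to 3136 without a library. Over 5 kb, the 64 were 74 to 160, and the 7 were 12 above either threshold and 22 to 31 without a library. Presence in fewer libraries is easier to meet, which raises all these counts. The replicate numbers, which both groups share, were not taken to pair the libraries: deviations of same-numbered libraries correlated at r = 0.10 over the shared regions, with 2 pairs only. No alternative for genes or gene lists was run, as genes could not be named.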

Other observations

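The tests of scaling, region ends, reads, the depth behind long regions, placement on chromosome 13 and other splits were chosen after the result was seen.

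High signals were also found in 3 regions that not all libraries held. At chr17:39983335-39985442 the highest signals were 1414 and 9218 in unsynchronized replicates 1 and 2 and 2739 in early G1 replicate 2, and early G1 replicate 1 had no call. At chr5:124078207-124078388 the unsynchronized libraries had 932 and 1238 and the early G1 libraries no call. At chr2:122201281-122201429 only the libraries unsynchronized replicate 2 and early G1 replicate 1 had calls, at 1381 and 745.

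Long regions of convergent transcription lacked a call in early G1 more often than the reverse. A candidate explanation is the lower inferred depth of the early G1 libraries. The number of regions over 10 kb ranked exactly as the inferred library size (rank correlation 1 over 4 libraries), so depth and group cannot be told apart for that number. For the 64 regions over 5 kb called in the unsynchronized libraries alone, a first test on total reads argued against depth, since all 39 of 5 to 10 kb and all 25 over 10 kb would exceed 10 times the 5th percentile of reads in early G1. Length alone nearly fixes that outcome, so it was replaced, after its result was seen, by reads per kb, where 36 of the 64 (56.25%) would exceed the 5th percentile of long regions called in early G1 (96.3), which leaves depth open. A change of nascent transcription in the early G1 cells, on either strand, stays open and untested, whether from the cell cycle phase or from nocodazole and the return to culture.

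Shared regions lay higher in early G1 by a median log2 change of 0.41. The tables argue against different region ends, since signal times length shifted by 0.41 too, and against few reads, since the 25% of regions with the most reads shifted by 0.40. The library constants may carry the shift, because unscaled reads shifted by -0.25 in the early G1 libraries, which were smaller by inferred size. Without a spike-in, a scaling effect and a general rise in early G1 cannot be told apart. Effects of nocodazole and of the return to culture cannot be told apart from those of early G1 either.

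The called regions lay close together on chromosome 13. The 17 regions formed 3 pairs within 1 Mb, all among the 3 regions at 21809885 to 22122063. In 10000 random draws of 17 tested regions the mean was 0.243 pairs (permutation p = 0.0038). This leaves chance placement open, since the closeness itself prompted the test and the draws ignore that neighbours correlate even between replicates. That neighbours changed together in this interval is not shown, since 3 of its 7 shared regions lay below 0. The hypothesis that these regions share a response to early G1 was not tested further.

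The hypothesis that neighbouring regions change together between the groups found no support beyond the correlation within the early G1 replicates. Neighbours within 100 kb correlated at r = 0.107 (Spearman 0.146) in the group difference over 2420 pairs across the genome, which are not independent replicates. They correlated at 0.0736 (0.133) in the difference of the unsynchronized replicates and at 0.162 (0.161) in that of the early G1 replicates. Each permutation p was 0.001, the smallest that 1000 permutations give, and 0.0017 after adjustment over 12 tests. The group value exceeded the higher replicate value by -0.055. The early G1 replicate difference thus correlated more than the group difference, and the unsynchronized replicate difference less.

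The call of 17 changed regions has few comparisons. The 4 libraries allow 3 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many as 17 regions, and the highest other gave 7. With the authors' scaling this comparison is uneven. The median shift of 0.41 between the groups adds to the changes of the real split and to the spread within the others. After each library was divided by its median, all 3 splits gave 0 regions.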
